A study of Homo sapiens with 47 samples.

How the data were processed

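Small RNA was sequenced from fractions enriched for extracellular vesicles (EVs), the membrane-bound particles that cells release. The fractions came from medium conditioned by human mesenchymal stem cells, multipotent stromal cells that can form bone, cartilage and fat. Cells of 3 donors were cultured, 1 from adipose tissue (donor A) and 2 from bone marrow (donors B and N). Each donor was grown in 4 cultures. In 3 of them the cells sat on microcarriers, small beads that give adherent cells a surface, and in the remaining one, labelled Suspension, no carrier was used. The carriers were rHS29/COL and rHS01/COL, which join collagen to recombinant heparan sulfate preparations of high (rHS29) and low (rHS01) sulfate density, and COL, commercial collagen carriers. Every culture was kept in microgravity or as a ground control and sampled on day 6 and day 9. These factors make 16 groups and 47 libraries, 3 per group (1 per donor) except Suspension on the ground on day 9, where the labels hold no library of donor A. Per the series' design text, every library is a pool of 3 biological replicates of 1 donor, so the spread between libraries of a group is a spread between donors and p-values do not measure the spread between cultures of 1 donor.

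Per the labels' protocols, RNA was isolated with exoRNeasy Midi columns in 14 µL, converted with the QIAseq miRNA kit, which adds unique molecular identifiers at reverse transcription, and sequenced on an AVITI instrument. Builds hg38 and GRCh38 are named in the submitters' processing notes. The aligner, the miRNA annotation release, the batches of libraries and sequencing, and whether identifiers were collapsed are not given in the sources used here. The deposited table holds 2632 mature human miRNAs by 47 libraries, with columns that the authors headed CPM. All 47 columns were matched to samples by name.

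The deposited values are a scaled signal, not plain CPM (counts scaled to a sum of 1e6), as the columns sum to 701603.9 to 1788211.9 (median 974075.1). In every library all values above 0 were whole multiples of the smallest one (100% within a tolerance of 0.001 of a whole number), so that whole counts could be recovered. Recovered totals were 50880 to 683498 per library (median 260708). The value of 1 count in the authors' table was 0.99675 to 1.004 times (median 1.0001) what edgeR's trimmed mean of M-values (TMM) scaling of those counts gives. The unit is therefore written below as scaled CPM. A floor of 3 counts corresponded to between 3.98 and 45.5 scaled CPM, depending on the library, and covers counting error only. At low depth a value of 0 is a limit, not an absence.

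The design, the alternatives, the named-miRNA rule and 23 lists of miRNAs were fixed before the data were examined. The design had named CPM, and was kept because the scaled values are used the same way. A miRNA was tested when it reached 10 scaled CPM in at least 6 of the 47 libraries. This left 421 of 2632 (1346 were above 0 in any library). The main test was limma 3.58.1 in R 4.3.3 on log2(value + 2), with a mean-variance trend, 1 coefficient per group and the donor as a block, over all 47 libraries. The block was part of the design because the 3 libraries of each group come from the same 3 donors throughout. After group means were removed, the median correlation was 0.22 between libraries of the same donor and -0.14 between libraries of different donors, and 45 of 47 libraries correlated best with their own donor. Tests were two-sided, with Benjamini-Hochberg adjustment over the 421 within a comparison and a threshold of 0.05. Fold changes are on the log2(value + 2) scale, which understates the change of scarce miRNAs, and their error is the standard error (SE). Levels are means with the standard deviation (SD) between libraries. Libraries of the 2 donor comparisons are repeated samples of 3 donors, so those p-values describe these donors and no wider group. The gravity, culture and day comparisons rest on repeated samples of the same 3 donors. Their p-values and counts of matched pairs or groups likewise describe these donors and no wider group.

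There were 16 comparisons. Gravity was tested over all cultures and days, on each day, in each culture, and for a different effect between days and between cultures (an F test). Cultures were tested as the mean of both heparan sulfate carriers (HS/COL) against COL, rHS29/COL against rHS01/COL, HS/COL against Suspension and COL against Suspension. Day 9 was tested against day 6, donor A against donors B and N, and donor B against donor N. The comparisons with Suspension use the same 11 Suspension libraries and are not independent of each other, so no overlap between their calls is given. Library measures were compared by permutation tests of matched differences with 100000 resamples.

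Named miRNAs were the 10 largest rises and falls among those past the threshold with the same sign in all 3 donors (for donor comparisons, in at least 14 of the 16 groups) and a mean of at least 50. Up to 4 called members of each list were also named, with no minimum of the mean. A comparison with fewer than 5 calls also names the 5 miRNAs with the lowest unadjusted p. Outside the rule, miR-320a-3p, miR-320b, miR-122-5p and miR-126-3p for gravity, miR-222-5p for gravity in Suspension and on day 9, miR-16-5p and miR-342-3p for HS/COL against Suspension, miR-122-5p and miR-126-3p for HS/COL against COL, and miR-1290 for rHS29/COL against rHS01/COL were chosen after their values were seen. Lists with 3 or more measured members (18 of 23) were tested with camera at its preset correlation of 0.01, with an estimated correlation and with fry as alternatives. They were tested in 8 comparisons. Lists overlap: miR-451a, miR-486-5p, miR-142-3p and miR-150-5p are both in the list reported as enriched in vesicles and in a blood cell list, and miR-1246 and miR-1290 are both in the vesicle list and in that of annotations resembling fragments of transfer or ribosomal RNA. Sequence overlap was not searched, so membership of that last list does not show that the reads of a miRNA are such fragments.

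The alternatives changed the pseudocount, the filter, the scaling (median-ratio, quantile, the most abundant miRNA left out), the block, the unit (1 value per donor), the weighting of libraries (array weights) and the libraries used, and ran edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered counts. Plain CPM, log10 depth as a covariate and leaving out the 7 libraries under 150000 counts were added after the data were seen.

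The fit was tested on simulated counts with 200 changed miRNAs. For gravity over all cultures, with 423 miRNAs in the step, it recovered 67.2% of 1.5-fold, 83.6% of 2-fold and 98.5% of 4-fold changes. For HS/COL against Suspension (421 miRNAs) it recovered 37.3%, 79.1% and 98.5%. For gravity within COL (426 miRNAs) it recovered 16.4%, 47.8% and 78.8%, and for donor A against the marrow donors (420 miRNAs) 64.2%, 83.6% and 97.0%. Among the calls, unchanged miRNAs numbered 1 of 167 for gravity over all cultures, 0 of 143 for HS/COL against Suspension, 5 of 100 for gravity within COL and 8 of 171 (4.68%) for donor A, and no changed miRNA was called with the wrong sign. In a separate simulation with no change at all, limma called 0 miRNAs in each of these 4 comparisons. The simulations took the authors' scaling factors as exact and held as many rises as falls. They held no response particular to a donor and, for donor A, no donor differences other than the changes set. These rates therefore do not cover false calls from scaling or from differences between donors. No pair of libraries of a group agreed within counting noise (lowest chi-square per degree of freedom 13.9 over 46 pairs).

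Hairpin genes were matched by name to the GENCODE release 29 annotation of GRCh38 (397 of the 421). Of those, 358 have a single hairpin, and 357 of these have the same start and end in RefSeq. Coordinates are 1-based and cover the hairpin. Mature miRNAs with several hairpins, or with near-identical relatives such as the miR-320 and let-7 families, are uncertain as to the locus.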

Results

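Small RNA of EV-enriched fractions from mesenchymal stem cell medium was profiled in 47 libraries, 24 from microgravity and 23 from ground controls, with 12 each from rHS29/COL, rHS01/COL and COL carriers and 11 from Suspension, to follow what the cells release on carriers of collagen and heparan sulfate in microgravity. Libraries held 50880 to 683498 recovered counts (median 260708). A median of 518 miRNAs was above 0 per library (range 336 to 667). The let-7 family, miRNAs that hold back proliferation and are abundant in differentiated cells, made up most of the signal. On average let-7a-5p took 23.9% of it (244283 ± 100774 scaled CPM, SD, n = 47), let-7b-5p 15.4%, let-7i-5p 8.09%, let-7f-5p 6.05% and let-7g-5p 3.95%. The remaining miRNAs of the 10 most abundant were miR-16-5p at 4.11%, miR-143-3p at 2.41%, miR-29a-3p at 2.29%, miR-24-3p at 1.77% and miR-320a-3p at 1.74%. miR-143-3p and miR-24-3p are abundant in stromal cells. miRNAs typical of epithelium (0 of 8), of pluripotent cells (0 of 8) and of the placental cluster on chromosome 19 (0 of 27) did not pass the filter on low values.

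Whether microgravity changed the released miRNAs was tested over all cultures and days. In microgravity 9 miRNAs were higher and 1 was lower than on the ground. miR-1290 rose 1.78-fold (log2 0.84 ± 0.15 SE, adjusted p = 0.0013, higher in 20 of 23 matched pairs), from 1150 ± 735 scaled CPM on the ground (SD, n = 23) to 1891 ± 1624 (n = 24). miR-1246 rose 1.83-fold (log2 0.88 ± 0.18, adjusted p = 0.0029, 20 of 23 pairs), from 6944 ± 4495 to 12258 ± 13339. Its microgravity mean was raised by 1 library at 66169, and the medians were 6942.5 on the ground and 10064.8 in microgravity. Both are short annotations whose sequences also occur in longer non-coding RNA. Among the miR-320 family, miR-320d rose 1.78-fold (log2 0.83 ± 0.17, 20 of 23 pairs) and miR-320c 1.60-fold (log2 0.67 ± 0.16, 19 of 23 pairs), whereas the far more abundant miR-320a-3p had log2 0.13 ± 0.08 and miR-320b 0.30 ± 0.14, neither past the threshold. miR-378a-3p, which lies in an intron of the metabolic coactivator gene PPARGC1B (chromosome 5, 149732825 to 149732890, GRCh38), rose 1.44-fold (log2 0.52 ± 0.11) in 22 of 23 pairs. miR-130a-3p, which targets the adipogenic regulator PPARG, rose 1.33-fold (log2 0.41 ± 0.09), and miR-199a-3p, abundant in mesenchymal cells, rose 1.29-fold (log2 0.37 ± 0.09). miR-619-5p (intron of SSH1, chromosome 12, 108836908 to 108837006) rose 2.33-fold (log2 1.22 ± 0.34) and miR-222-5p 1.41-fold (log2 0.50 ± 0.14, 16 of 23 pairs). In Suspension alone miR-222-5p had log2 -0.24 ± 0.30 (higher in 1 of 5 pairs), and on day 9 alone 0.09 ± 0.20 (6 of 11 pairs, adjusted p = 0.89). miR-619-5p had log2 2.93 ± 0.66 in COL, 0.43 ± 0.66 in rHS29/COL, 0.44 ± 0.66 in rHS01/COL and 1.07 ± 0.70 in Suspension. The F test between cultures did not separate these (adjusted p = 0.47). On day 9 alone miR-619-5p had 0.51 ± 0.48 (adjusted p = 0.65). miR-4492 fell to 0.64 times its ground level (log2 -0.64 ± 0.16, lower in 17 of 23 pairs). Adjusted p was 0.0029 for miR-320d, 0.0038 for miR-378a-3p, 0.0088 for miR-130a-3p, 0.0104 for miR-320c, 0.0126 for miR-4492, 0.0132 for miR-199a-3p, 0.0378 for miR-619-5p and 0.0469 for miR-222-5p.

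Of the lists, the let-7 family was lower in microgravity as a group (median log2 -0.13 over 9 members, adjusted p = 0.0113), although none of its members was called, also when adjusted over the list alone. With an estimated correlation the adjusted p was 0.94, and under quantile normalization it was 0.11. The miRNAs reported as enriched in vesicles were higher (median log2 0.20, adjusted p = 0.0194 and 0.84 with an estimated correlation). All 10 measured members had a positive log2 value and 2 of 10 were called, miR-1246 and miR-1290, as many as adjusted over the list alone. Under median-ratio and quantile scaling this list had adjusted p of 0.057 and 0.072. In the adipogenic list 2 of 13 members rose, miR-378a-3p and miR-130a-3p, and in the mesenchymal list 1 of 16, miR-199a-3p. In the list of fragment-like annotations 3 of 14 rose. No member was called in the osteogenic (9 measured), chondrogenic (8), mechanosensitive (9), hypoxia (4), p53 and senescence (6), inflammation (4), miR-29 (4), miR-17-92 (9), chromosome 14q32 (35), erythroid (4), leukocyte (8), striated muscle (3) and neuronal (3) lists. miR-122-5p of liver had log2 0.08 ± 0.24 and miR-126-3p of endothelium 0.13 ± 0.21. Library measures did not separate microgravity from ground: 40.2 more miRNAs were detected (16 of 23 pairs, permutation p = 0.138, adjusted p = 0.39) and the share of let-7a-5p differed by -1.11 percentage points (7 of 23 pairs higher, permutation p = 0.41).

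The count of 10 depended on the donors. It was 7 without donor A (4 of the 10 among them), 0 without donor N, 2 without donor B, 17 without the single library of donor B on rHS01/COL in microgravity on day 6, and 5 with 1 value per donor. Under quantile scaling 7 were higher and 3 lower, under median-ratio scaling 5 and 2, and without the donor block 9 were called. edgeR on the recovered counts called 9 (7 of them among the 10) and DESeq2 21 (9 of them).

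**Figure D1:**
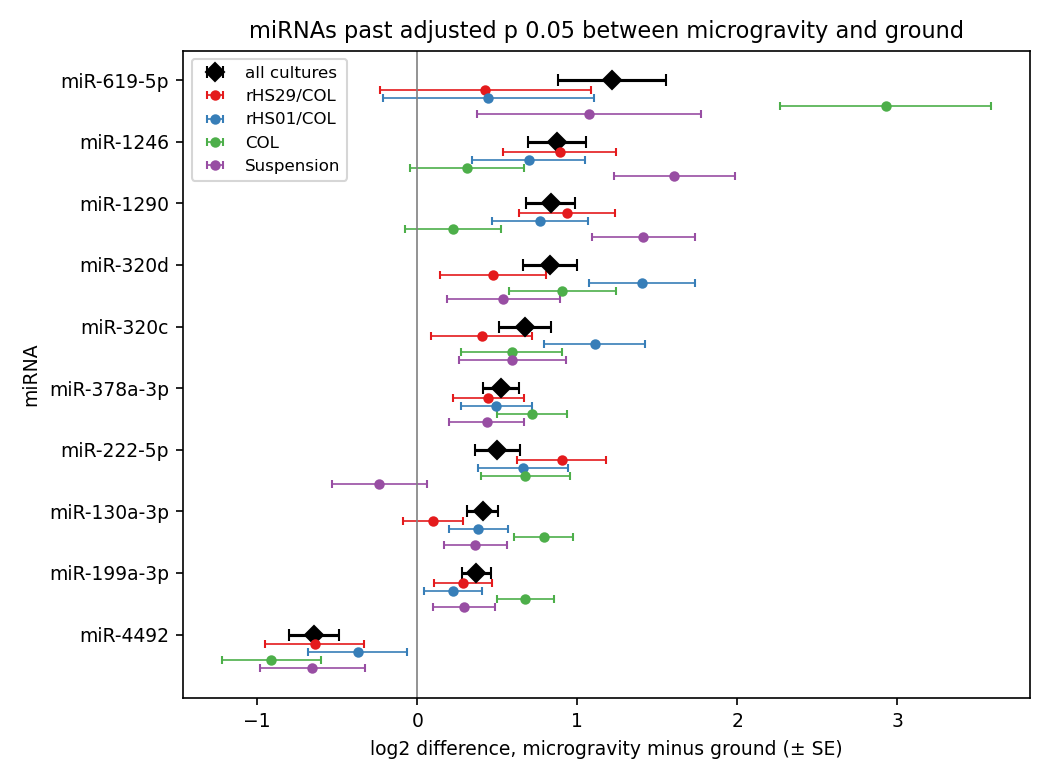
Log2 difference between microgravity and ground (horizontal axis, points with SE bars) for the 10 miRNAs past the threshold over all cultures, with the value in all cultures as black diamonds and in each culture as coloured circles. In Suspension miR-1246 and miR-1290 had log2 1.61 and 1.41, and in COL miR-619-5p had 2.93, but a test for a different effect between cultures passed the threshold for none of the 421 miRNAs.

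By day, 4 miRNAs were higher in microgravity on day 6. miR-1290 rose 2.03-fold (log2 1.02 ± 0.21, adjusted p = 0.0097), miR-1246 1.99-fold (log2 1.00 ± 0.25, adjusted p = 0.0325) and miR-222-5p 1.88-fold (log2 0.91 ± 0.20, adjusted p = 0.0097), each in 10 of 12 pairs, and miR-619-5p 3.80-fold (log2 1.93 ± 0.47, adjusted p = 0.0259, 9 of 12 pairs). Among those not called on day 6 were miR-19a-3p at log2 -1.71 (adjusted p = 0.073) and miR-550a-5p at 1.25. On day 9 another 2 were higher, each in 11 of 11 pairs: miR-193b-3p 4.91-fold (log2 2.29 ± 0.52, adjusted p = 0.032, from 9.14 ± 9.05, n = 11, to 44.8 ± 38.6, n = 12), and miR-378a-3p 1.60-fold (log2 0.68 ± 0.16, adjusted p = 0.032). miR-193b-3p (chromosome 16, 14303967 to 14304049, intron of MIR193BHG) takes part in adipocyte formation. Its ground mean of 9.14 on day 9 lay among the floors of 3 counts of those 11 libraries, 5.29 to 43.0 scaled CPM. The fold of miR-193b-3p thus rests on few counts. miR-320d at log2 0.94 was not called on day 9 (adjusted p = 0.057). The effect of gravity was not shown to differ between the days: limma called 0 of 421 (32 at an unadjusted p under 0.05), as did edgeR (33) and DESeq2 (37), and the lowest adjusted p, 0.051, was that of miR-193b-3p. Without the donor block, 2 were called on day 6 and 2 on day 9. Under quantile normalization 2 were higher and 3 lower on day 9. Neither day 9 call held without donor A, without donor B or without donor N (log2 of miR-193b-3p 2.06, 2.47 and 2.36). The day 9 count was 0 with edgeR and 0 without the 7 libraries under 150000 counts. The day 6 count was 0 with 1 value per donor, 2 without donor A, 1 without donor B and 1 without donor N.

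Within cultures the groups were small (6 against 6, in Suspension 6 against 5). In Suspension miR-1246 rose 3.04-fold (log2 1.61 ± 0.38) and miR-1290 2.66-fold (log2 1.41 ± 0.32, adjusted p = 0.0278 for both), each in 5 of 5 pairs. The 6 microgravity libraries held 995 to 2475 scaled CPM of miR-1246 and the 5 ground libraries 473 to 885. In COL, miR-619-5p rose 7.62-fold (log2 2.93 ± 0.66) and miR-130a-3p 1.73-fold (log2 0.79 ± 0.19, adjusted p = 0.0275 for both), each in 6 of 6 pairs, and miR-199a-3p had log2 0.68 (adjusted p = 0.055). In rHS01/COL limma called 0 miRNAs (49 at an unadjusted p under 0.05), edgeR 0 and DESeq2 1, and the value nearest the threshold was miR-320d at log2 1.41 ± 0.33 (adjusted p = 0.061, 6 of 6 pairs). In rHS29/COL limma, edgeR and DESeq2 called 0 each (24, 40 and 33 at an unadjusted p under 0.05). There miR-222-5p had log2 0.90 ± 0.28 and miR-1290 0.94 ± 0.30, and their adjusted p was 0.64. The difference between cultures was itself tested, and limma called 0 (37 at an unadjusted p under 0.05), as did edgeR (33) and DESeq2 (44), with adjusted p of 0.47 for miR-1290 and 0.50 for miR-1246. Without the donor block, 0 were called in Suspension and 1 in COL. In Suspension 3 were called without donor A, and 0 without donor B or without donor N. In COL, 15 were higher and 2 lower under plain CPM, and 2 and 2 under quantile normalization. Both COL calls were lost with edgeR, with log10 depth as a covariate, and without the libraries under 150000 counts.

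**Figure D2:**
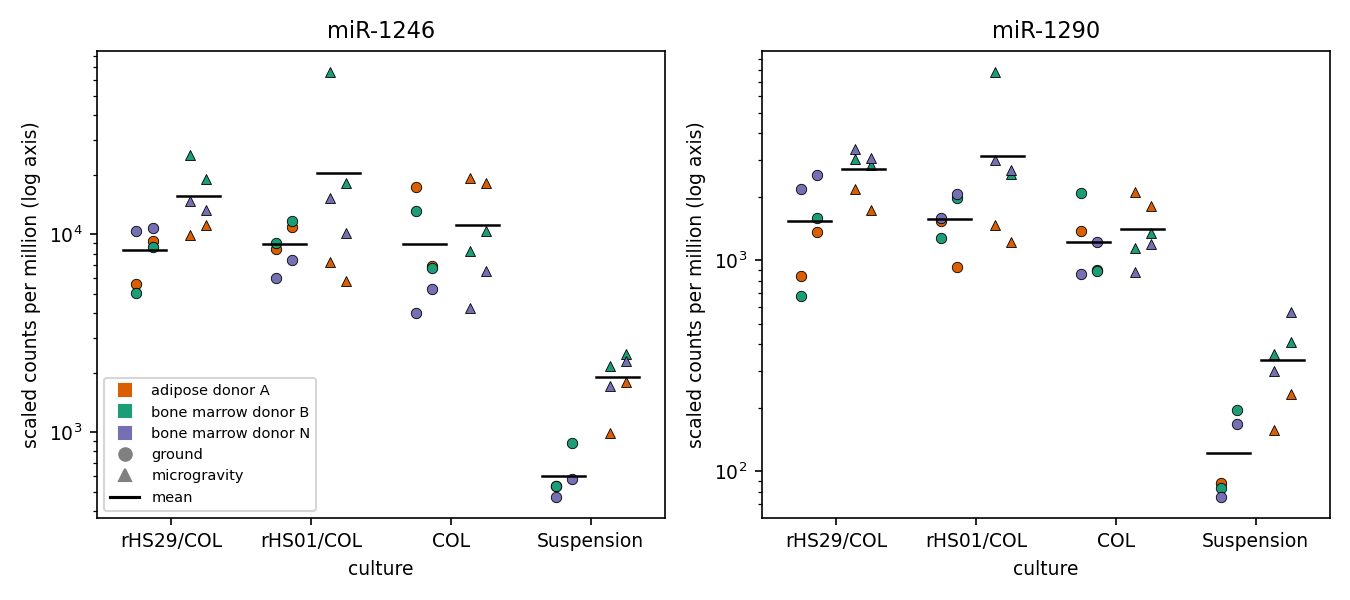
Scaled CPM (log axis) of miR-1246 and miR-1290 in each of the 47 libraries, by culture, with ground libraries as circles, microgravity libraries as triangles, donors by colour, day 6 left and day 9 right within a column, and the mean as a line. Suspension held 1310 ± 782 of miR-1246 and 239 ± 156 of miR-1290 (n = 11), against 10003 ± 5556 and 1316 ± 455 in COL (n = 12).

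Carriers were compared with Suspension culture. On the HS/COL carriers 49 miRNAs were higher and 42 lower than in Suspension. miR-1290 was 10.1-fold higher (log2 3.33 ± 0.19, adjusted p = 3.5e-17), at 2226 ± 1414 (n = 24) against 239 ± 156 (n = 11), and miR-1246 was 10.5-fold higher (log2 3.39 ± 0.23, adjusted p = 2.5e-15), both in 11 of 11 matched groups. MIR1290 lies on chromosome 1 (18897071 to 18897148) in an intron, and MIR1246 on chromosome 2 (176600980 to 176601052) between genes. miR-139-5p (intron of PDE2A, chromosome 11) was 8.28-fold higher, and miR-4485-3p and miR-1973, both annotated in exons of nuclear copies of mitochondrial ribosomal RNA (MTRNR2L8 and MTRNR2L13), were 7.20-fold and 8.54-fold higher. miR-4455 was 7.36-fold higher. Lower on HS/COL than in Suspension were miR-483-5p, from an intron of IGF2 (chromosome 11, 2134134 to 2134209), at 0.17 times (log2 -2.52 ± 0.39, 28.4 ± 30.5 against 193 ± 123, lower in 11 of 11), miR-199b-5p at 0.43 times, miR-1180-3p at 0.43 times (log2 -1.21 ± 0.30), miR-99a-5p at 0.47 times, miR-127-5p at log2 -1.07, miR-450a-5p at log2 -1.05, miR-1185-1-3p at log2 -0.98, miR-21-3p at log2 -0.84, miR-4492 at log2 -0.83 and miR-5585-3p at log2 -1.92.

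miRNAs of blood cells, endothelium and liver, lists meant to show RNA of other origin, were higher on HS/COL. In the erythroid list 3 of 4 members rose (adjusted p = 0.0014, and adjusted p = 0.039 with an estimated correlation): miR-451a 11.8-fold (log2 3.56 ± 0.50), miR-486-5p 7.73-fold (2.95 ± 0.36) and miR-144-3p 6.16-fold, with miR-16-5p, which stromal cells also hold in abundance, at log2 -0.01 ± 0.12. In the list of platelet, myeloid and lymphoid miRNAs 5 of 8 rose and 1 fell (adjusted p = 0.0236, and adjusted p = 0.11 with an estimated correlation). miR-223-3p of myeloid cells rose 13.1-fold (log2 3.71 ± 0.43), from 2.72 ± 4.88 with 8 of 11 Suspension libraries at 0 to 61.2 ± 73.8. Without the ground Suspension library of donor N on day 6 the Suspension mean of miR-223-3p was 1.66 ± 3.55. miR-142-3p rose 9.42-fold and miR-150-5p 7.39-fold, and miR-342-3p fell to 0.65 times. miR-126-3p and miR-126-5p of endothelium (intron of EGFL7, chromosome 9, 136670602 to 136670686) rose 3.90-fold and 3.49-fold. miR-122-5p of hepatocytes (chromosome 18, 58451074 to 58451158) rose 4.29-fold (log2 2.10 ± 0.30), from 635 ± 310 to 4543 ± 9262, in 11 of 11 groups. The library of donor B on rHS01/COL in microgravity on day 6 held 46849 of it, and without that library the HS/COL mean of miR-122-5p was 2704 ± 2187 and the log2 difference 1.98. The neuronal list had 2 of 3 higher (miR-129-5p log2 2.31, miR-128-3p 0.58) and the striated muscle list 1 of 3 (miR-206, log2 1.62, listed at 0 in 9 of 11 Suspension libraries), without passing the list test. The list reported as enriched in vesicles had 7 of 10 higher and none lower (adjusted p = 6.9e-09, and adjusted p = 0.0030 with an estimated correlation), and of these 7, miR-451a, miR-486-5p, miR-150-5p and miR-142-3p are also in the blood cell lists. Of the fragment-like annotations 7 of 14 were higher, such as miR-3182 (3.61-fold) and miR-7704 (1.93-fold), with an adjusted p = 6.3e-04 and an adjusted p = 0.11 with an estimated correlation. Adjusted over the list alone, the counts were 3 erythroid, 5 higher and 2 lower for leukocytes, 7 for vesicles and 8 for fragment-like annotations.

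The let-7 family was lower on HS/COL, with 5 of 9 members called and none higher, also adjusted over the list alone (adjusted p = 0.0044, but 0.48 with an estimated correlation). let-7c-5p fell to 0.57 times (log2 -0.82 ± 0.15), let-7a-5p to 0.64 times (-0.64 ± 0.15), let-7f-5p had -0.45 and let-7b-5p -0.41. With quantile normalization let-7f-5p and let-7b-5p turned to 0.17 and 0.016 and the list had an adjusted p of 0.38. Under plain CPM the median of the list went from -0.31 to -0.07, with 4 of 9 members above 0 (adjusted p = 0.0155). let-7a-5p took 21.5% ± 3.8 of the signal on HS/COL (n = 24) and 28.7% ± 4.6 in Suspension (n = 11), higher on HS/COL in 1 of 11 groups (permutation p = 0.0020, adjusted p = 0.030). Of stromal miRNAs 2 of 16 rose, miR-138-5p 2.72-fold (log2 1.44 ± 0.25) and miR-145-5p 1.79-fold (log2 0.84 ± 0.29). In the osteogenic list miR-23a-3p rose (log2 0.81) and miR-196a-5p (-0.75), miR-204-5p (-1.43) and miR-148a-3p (-1.23) fell. In the adipogenic list miR-378a-3p (0.81) and miR-27a-3p (0.57) rose and miR-30a-5p (-0.49) and miR-130a-3p (-0.46) fell. The imprinted cluster at 14q32, active in mesenchymal cells, had 4 of 35 lower and none higher, miR-411-5p (-0.61), miR-379-5p (-0.68), miR-134-5p (-0.53) and miR-127-3p (-0.43). None of these 4 lists passed the list test. limma called 91 in all, 24 with 1 value per donor and 47 without donor N. Relative to the deposited scaling, plain CPM moved the median of all miRNAs from -0.06 to 0.17 and gave 72 higher and 17 lower. With the most abundant miRNA left out 60 were higher and 29 lower, and with quantile normalization 44 and 65. edgeR called 106, of which 87 were among the 91, and DESeq2 118.

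**Figure D3:**
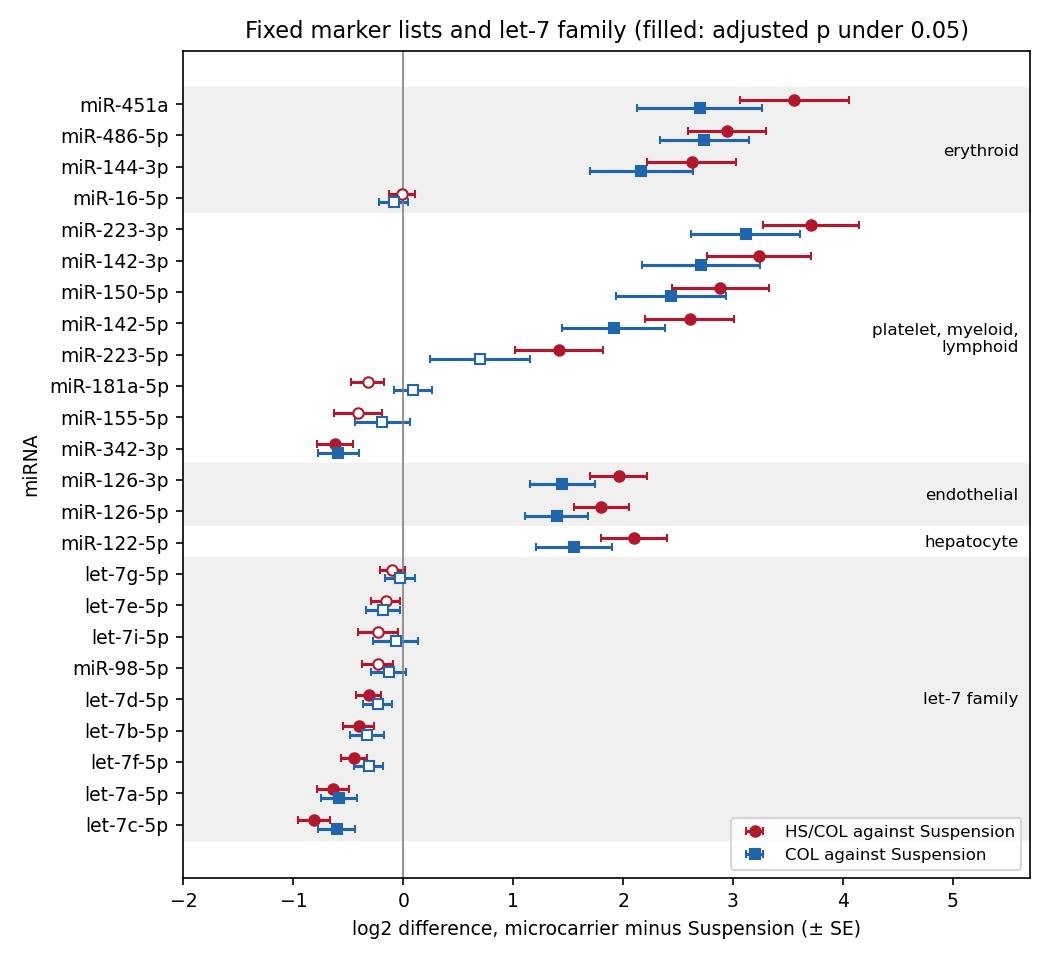
Log2 difference between carriers and Suspension (horizontal axis, SE bars) for the miRNAs of blood cell, endothelial and liver lists and of the let-7 family, for HS/COL (circles) and COL (squares), filled where the adjusted p was under 0.05. miR-223-3p, at log2 3.71 on HS/COL and 3.11 on COL, lay far from 0, whereas let-7 members lay between -0.82 and -0.03, of which let-7f-5p and let-7b-5p on HS/COL turned above 0 with quantile normalization.

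Commercial COL carriers against the same Suspension libraries gave 29 higher and 19 lower. miR-1290 was 6.53-fold higher (log2 2.71 ± 0.22, adjusted p = 2.6e-12) and miR-1246 8.29-fold (log2 3.05 ± 0.26), each in 11 of 11 groups. miR-486-5p was 6.68-fold, miR-223-3p 8.66-fold, miR-451a 6.49-fold, miR-126-3p 2.73-fold, miR-122-5p 2.94-fold, miR-139-5p 4.37-fold and miR-4497 3.02-fold higher. The erythroid list had 3 of 4 higher (adjusted p = 0.0020, and adjusted p = 0.048 with an estimated correlation) and the leukocyte list 4 of 8 higher and 1 lower (adjusted p = 0.0131, and adjusted p = 0.063 with an estimated correlation). The vesicle list had 6 of 10 higher (adjusted p = 1.4e-08, and adjusted p = 0.0038 with an estimated correlation) and the fragment-like list 3 of 14, or 7 higher and 1 lower adjusted over the list alone (adjusted p = 5.0e-05, and adjusted p = 0.052 with an estimated correlation). miR-29b-3p, which represses collagen transcripts, rose 1.73-fold (log2 0.79 ± 0.20) as the only called member of 4 in its family. miR-138-5p rose 2.74-fold and miR-125b-5p 1.43-fold. Of 14q32 miRNAs 2 of 35 fell, miR-134-5p to 0.51 times (log2 -0.98 ± 0.17, lower in 11 of 11) and miR-127-3p to 0.69 times (adjusted p = 0.034 for the list, 0.66 with an estimated correlation, and 0.15 under plain CPM). Of the let-7 family 2 of 9 fell, let-7a-5p (-0.58) and let-7c-5p (-0.61), with an adjusted p = 0.0150 for the list, 0.66 with an estimated correlation, 0.43 under quantile normalization and 0.058 under plain CPM, where the median went from -0.23 to -0.04 with 4 of 9 above 0. Adipogenic miR-30a-5p (-0.57), miR-130a-3p (-0.54) and miR-130b-3p (-0.51) fell and miR-378a-3p rose (0.54). Other falls were miR-574-5p (-0.63), miR-744-5p (-0.77) and miR-196a-5p (-0.69). limma called 48, against 23 without the donor block, 22 without donor B, 13 without donor N and 4 with 1 value per donor. Under plain CPM 38 were higher and 8 lower, and with the most abundant miRNA left out 32 and 10. edgeR called 55 (46 among the 48) and DESeq2 64.

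HS/COL was compared with COL, commercial carriers that differ from HS/COL in make as well as in heparan sulfate, and 6 miRNAs were called. miR-222-5p was 1.57-fold higher on HS/COL (log2 0.65 ± 0.17, 608 ± 246, n = 24, against 393 ± 166, n = 12, in 11 of 12 groups), miR-615-3p, which lies in the HOXC cluster region, 1.88-fold higher (log2 0.91 ± 0.23, 11 of 12) and let-7b-3p 1.70-fold higher (log2 0.77 ± 0.20, 10 of 12). miR-206, a skeletal muscle miRNA (chromosome 6, 52144349 to 52144434), was higher at log2 1.798 ± 0.443 in 12 of 12 groups. It was listed at 0 in 11 of 12 COL libraries and reached 33.8 ± 82.7 on rHS01/COL and 6.70 ± 9.61 on rHS29/COL (SD, n = 12 each). The miR-206 mean on rHS01/COL fell to 10.1 ± 11.1 without the ground library of donor B on day 6 (294 in that library), and that on rHS29/COL to 4.36 ± 5.42 without the ground library of donor N on day 9. The miR-206 call held in 38 of 50 fits that left out a library or a donor. miR-425-5p fell to 0.72 times (log2 -0.48 ± 0.13) and miR-5585-3p to 0.19 times (log2 -2.37 ± 0.51). The adjusted p was 0.0141 for miR-5585-3p and 0.0395 for the others. The lists gave no call, the lowest being the vesicle list (median log2 0.27, adjusted p = 0.058, 0.034 under plain CPM, 0.042 with the most abundant miRNA left out, and adjusted p = 0.50 with an estimated correlation). The blood cell, endothelial and liver miRNAs had positive values that were not called, such as miR-122-5p at 0.55 ± 0.29 and miR-126-3p at 0.51 ± 0.25. Without the donor block 2 were called, with 1 value per donor 1, and without donor N 0. Without donor A, 2 were higher and 5 lower (1 of the 6 among them), and without donor B 3 higher and 5 lower (3 of the 6). edgeR called 8 (4 of the 6) and DESeq2 20 (5 of the 6), and under quantile normalization 3 were higher and 5 lower.

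Sulfate density was compared as rHS29/COL against rHS01/COL, related preparations tested at the same days. limma called 0 miRNAs (18 at an unadjusted p under 0.05), as did edgeR (14) and DESeq2 (16), and 0 in microgravity alone (36) or on the ground alone (22). The lowest p values were those of miR-770-5p (log2 1.25 ± 0.42, 16.8 ± 5.6 against 8.34 ± 7.03, n = 12 each), miR-758-5p (1.21), miR-450b-5p (1.15), miR-4286 (1.14) and miR-1270 (1.10), with an adjusted p of 0.70. The 95% interval of the difference lay within 1 log2 unit of 0 for 233 of 421 miRNAs (55.3%), and for 66 of the 69 with a mean of at least 1000. For miR-1290 it ran from -0.48 to 0.38. Smaller differences, and those of scarce miRNAs, were not resolved. No list passed the threshold, the lowest being the erythroid and striated muscle lists (adjusted p = 0.068 for both).

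Day 9 against day 6 also gave 0 calls with limma (23 at an unadjusted p under 0.05), edgeR (28) and DESeq2 (29). The lowest p values belonged to miR-134-5p (log2 0.39 ± 0.12, 18 of 23 pairs), miR-548d-5p (0.94), miR-30e-5p (0.30), miR-942-5p (0.79) and miR-1-3p (1.47). The adjusted p was 0.58 for the first 4 of these. No list passed the threshold.

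The adipose donor was compared with the bone marrow donors. In the adipose donor 64 miRNAs were higher and 94 lower than in the bone marrow donors. miR-335-5p, from an intron of the imprinted gene MEST (chromosome 7, 130496111 to 130496204), was 12.6-fold higher (log2 3.65 ± 0.33, adjusted p = 8.7e-12), at 2719 ± 1880 (n = 15) against 267 ± 238 (n = 32). The clustered miR-497-5p and miR-195-5p (chromosome 17, 7017911 to 7018022 and 7017615 to 7017701), which repress the cell cycle, were 3.91-fold and 2.80-fold higher. miR-140-5p and miR-140-3p, cartilage miRNAs from an intron of WWP2, were 2.68-fold and 2.15-fold higher, miR-224-5p 2.49-fold and miR-218-5p 2.10-fold. Lower in the adipose donor were miR-196a-5p, from the HOX gene clusters, at 0.17 times (log2 -2.54 ± 0.13, adjusted p = 2.2e-19, 888.5 ± 231 against 5775 ± 2662), miR-30a-5p at 0.39 times, miR-483-5p at 0.15 times, miR-12136 at 0.19 times, miR-4484 at 0.14 times and miR-34a-5p, a p53 target, at 0.50 times. miR-10a-5p, from the HOXB cluster, was 1.86-fold higher in 15 of 15 groups.

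By list, 5 of 9 let-7 members were higher in the adipose donor (adjusted p = 0.0188, 0.58 with an estimated correlation, 0.24 under quantile normalization), led by let-7i-5p at 3.39-fold (log2 1.76 ± 0.15), with let-7c-5p at 0.90, miR-98-5p at 0.75 and let-7b-5p at 0.66. In the osteogenic list 6 of 9 were higher and 2 lower, in the chondrogenic list 4 of 8 higher and 2 lower, in the stromal list 8 of 16 higher (miR-143-3p 1.76-fold, miR-125b-5p 1.57-fold) and 3 lower (miR-21-5p 0.63 times), and in the mechanosensitive list 3 higher and 3 lower of 9. None of these passed the list test. Of the 14q32 cluster 12 of 35 were lower and 1 higher (adjusted p = 0.058, but 0.037 under plain CPM), such as miR-376a-3p (-1.08), miR-323a-3p (-1.02) and miR-376c-3p (-0.83). In the leukocyte list 6 of 8 were lower (adjusted p = 0.0188, 0.21 with an estimated correlation), miR-142-3p at 0.23 times and miR-223-3p at 0.33 times among them. In the erythroid list miR-144-3p (0.25 times), miR-451a (0.32 times) and miR-486-5p (log2 -1.20) were lower and miR-16-5p was higher (log2 0.28), and the list did not pass (adjusted p = 0.35). Endothelial miR-126-3p at 0.41 times and liver miR-122-5p at 0.35 times were lower as single miRNAs, as these lists were too short for a list test. The blood cell, endothelial and liver lists were meant to show RNA of other origin. Whether the donors differed in the share of such RNA was not tested. The vesicle list was lower in 7 of 10 (adjusted p = 0.043, 0.58 with an estimated correlation, and 0.14 under quantile normalization). limma called 158, edgeR 165 (151 among them) and DESeq2 172. Plain CPM moved the median of all miRNAs to -0.24 and gave 38 higher and 138 lower, and leaving out the most abundant miRNA moved it to -0.31 and gave 39 higher and 154 lower. The comparison sets 1 donor against 2 and does not separate tissue from donor.

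**Figure D4:**
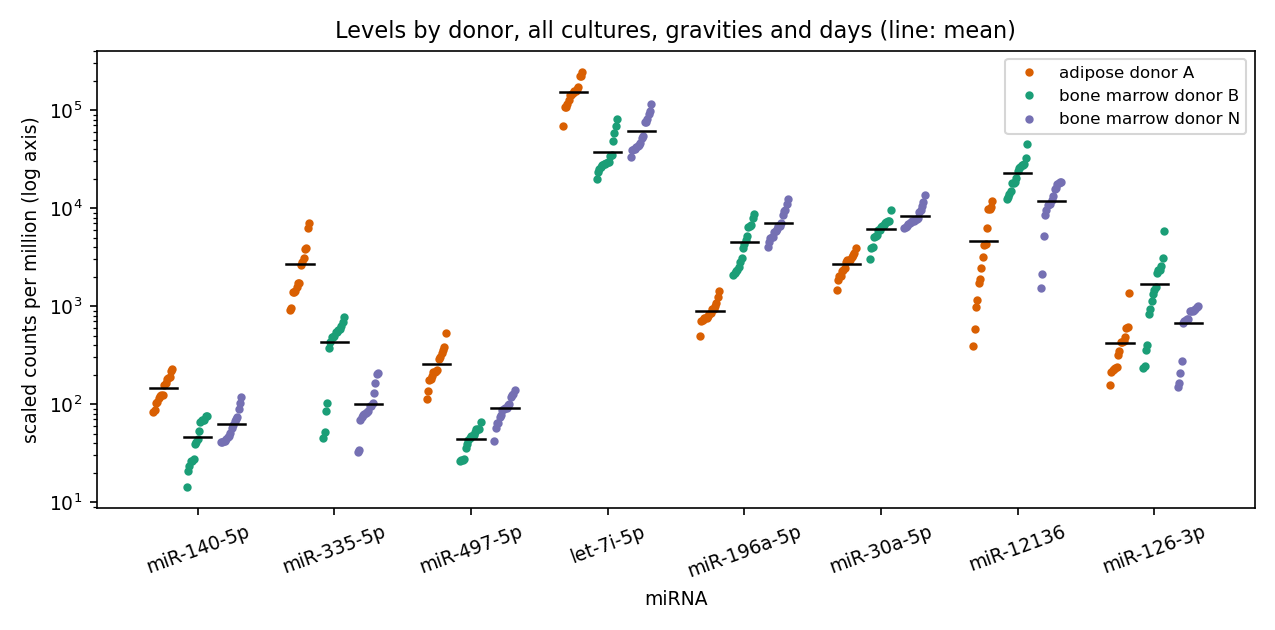
Scaled CPM (log axis) of 8 miRNAs in each library by donor, sorted within a donor, with the mean as a line. Over all cultures miR-335-5p had means of 2719 in donor A, 432 in donor B and 102 in donor N, and miR-196a-5p 889, 4501 and 7049. For miR-335-5p the order of donors B and N did not hold in every group, as the lowest Suspension library in microgravity (45.1) was of donor B.

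The bone marrow donors also differed, with 15 miRNAs higher and 27 lower in donor B than in donor N. Donor B had more miR-335-5p (3.53-fold, log2 1.82 ± 0.37), miR-4485-3p (2.71-fold), miR-12136 (2.18-fold), miR-126-3p (2.02-fold), miR-122-5p (1.98-fold) and 14q32 miRNAs miR-432-5p (1.47-fold, 16 of 16 groups), miR-376b-3p (1.58-fold) and miR-409-3p (1.27-fold). The rise of miR-335-5p did not hold in every group, as the lowest Suspension library in microgravity (45.1 scaled CPM) was of donor B. Donor B had less miR-34a-5p (0.53 times, log2 -0.92 ± 0.16, adjusted p = 1.4e-04), miR-10a-5p (0.69 times, lower in 16 of 16), miR-497-5p (0.50 times), miR-195-5p (0.50 times), miR-196a-5p (0.60 times), let-7i-5p (0.60 times) and the inflammation-linked miR-146b-5p (0.44 times). By list, stromal miRNAs were lower (1 of 16 called, 6 adjusted over the list alone, adjusted p = 0.026, 0.49 with an estimated correlation), as were mechanosensitive ones (2 of 9, adjusted p = 0.043, 0.48 with an estimated correlation), and 14q32 miRNAs were higher (3 of 35, adjusted p = 0.026, 0.49 with an estimated correlation). The first 2 of these were not past the threshold under plain CPM (0.090 for both), nor the third under quantile normalization (0.17). limma called 42, edgeR 41 (33 among them) and DESeq2 63. Median-ratio scaling gave 21 higher and 21 lower, plain CPM 18 and 16, and leaving out the most abundant miRNA 20 and 16. With log10 depth as a covariate 20 were called and without the libraries under 150000 counts 26. Depth differed between these 2 donors, with a median of 220434.5 recovered counts in donor B and 371078 in donor N. No library of donor N was under 150000 counts (lowest 206236). Depth as a cause of a part of these calls therefore stays open. For miR-126-3p and miR-122-5p a different share of RNA of other origin was not tested.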

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

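The tests of carry-over, depth, scaling and shared miR-320a-3p reads below, and the test of a common source with miR-1246 and miR-1290, were chosen after the result was seen, and the other splits of the labels were planned. Each check took 1 quantity in the 6 or 5 libraries of 1 culture and gravity, which mix donors and days. A library far from the others was found in 9 of 120 checks. A rate of 1 in 20 would mark 6, but the checks share libraries, so 6 is a rough guide and not a test. The sum of values stood highest in donor B on day 6 on rHS01/COL in microgravity (1788211.9, next 1146899.2), in donor A on day 9 on COL in microgravity (1140667.1, next 907028.9) and in donor A on day 6 on rHS01/COL on the ground (1295144.7, next 837130.8). In COL in microgravity, donor A on day 9 also had the highest miR-320d (2025.4, next 1058.2) and miR-320c (4195.7, next 2122.1) and the lowest miR-222-5p (208.55, next 431.63), and donor A on day 6 the highest miR-199a-3p (16010.8, next 11634.2). In COL on the ground, donor N on day 9 had the lowest miR-378a-3p (131.05, next 222.12). In Suspension on the ground, donor A on day 6 had the lowest miR-222-5p (75.69, next 280.13). No miRNA of 35 checked moved in opposite directions in every library of 2 cultures or days (105 checks).

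The 11 blood cell, endothelial and liver miRNAs called higher on HS/COL than in Suspension, the comparison they were picked on, rose there by a mean log2 of 2.62. On COL they rose by 2.08 over the same Suspension libraries, so the COL value is not an independent check. With log10 depth as a covariate the rise was 2.53 ± 0.35 on HS/COL and 2.01 ± 0.38 on COL, and the lowest over the 4 other scalings was 2.45 ± 0.30 and 1.96 ± 0.34, which argues against lower depth and the authors' scaling factors. A larger share of RNA carried over from 1 outside source, such as a medium supplement, predicts that these miRNAs vary together, and over the 36 carrier libraries miR-122-5p and the blood cell miRNAs correlated at r = 0.747 with group and donor means removed (rank correlation 0.818, adjusted permutation p = 2.0e-05). On HS/COL the rises were unequal, 2.87 ± 0.36 for 8 blood cell miRNAs, 1.88 ± 0.26 for 2 endothelial ones (0.97 lower than blood over 11 matched groups, exact p = 0.0117) and 2.10 ± 0.34 for miR-122-5p (0.77 lower, exact p = 0.0215). How much of each miRNA the cells themselves release was not measured, so a single source is not shown, and release by cells on carriers stays open, as untested.

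Higher levels of 9 miRNAs in microgravity were weighed against depth, scaling and shared reads. Their mean log2 rise was 0.73 with log10 depth as a covariate, and the lowest over the 4 other scalings was 0.61. This argues against depth and scaling as the whole cause of the mean rise. The 9 were picked under the deposited scaling, and fewer miRNAs were called under plain CPM or with the most abundant miRNA left out, so single calls do depend on scaling. miR-320c and miR-320d rose by 0.63 log2 more than miR-320a-3p (19 of 23 pairs, permutation p = 8.4e-04 before adjustment). By the rule first written, which asked for an unadjusted p under 0.05, this argued against reads shared with miR-320a-3p. Both miRNAs were picked from 421 because they were called, however, and an adjustment for that (adjusted p = 0.35) was added after the value was seen. By it, shared reads stay open for these 2. An effect of gravity stays open as a hypothesis, since it was found and tested on the same libraries, and so does the handling of microgravity cultures, which the labels do not separate from gravity. All 24 microgravity libraries are numbered before the 23 ground ones, and batches are not given. A batch of isolation, library preparation or sequencing that followed this order cannot be told apart from gravity.

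Between the adipose and the bone marrow donors 158 miRNAs differed. All 158 remained past the threshold with log10 depth as a covariate and at least 131 under the 4 other scalings, which argues against depth or the scaling factors as the whole cause. Tissue and donor cannot be separated with 1 adipose donor, so a difference of tissue stays untested. Carry-over, weighed above for blood cell, endothelial and liver miRNAs on carriers, was not tested between donors and stays open for those among the 158.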

How the results depend on the processing

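Plain CPM, log10 depth as a covariate and the fit without libraries under 150000 counts were chosen after the result was seen. Counts of called miRNAs beyond 1.5 times the reported one follow, and the cause was not tested. For gravity over all cultures (10) they were 6 with the most abundant miRNA left out, 5 with donor as the unit, 26 with array weights, 21 with DESeq2 and 6 with plain CPM. On day 6 (4) they were 2 with no filter, 2 with no block, 0 with donor as the unit, 0 with only the groups compared, 7 with DESeq2 and 8 with the depth covariate. On day 9 (2) they were 0 with a pseudocount of 0.5, no filter, median-ratio scaling, edgeR or without low-depth libraries, 7 with a mean of 100 or more, 5 with quantile normalization, 4 with the most abundant left out or the depth covariate, 52 with donor as the unit, 8 with only the groups compared, 35 with array weights and 10 with DESeq2. In rHS01/COL (0) they were 1 with a mean of 100 or more, array weights or DESeq2 and 2 with the depth covariate. In COL (2) they were 6 with a pseudocount of 10 or a mean of 100 or more, 4 with quantile normalization, 1 with no block, 42 with donor as the unit, 33 with array weights, 10 with DESeq2, 17 with plain CPM, and 0 with median-ratio scaling, only the groups compared, edgeR, the depth covariate or without low-depth libraries. In Suspension (2) they were 1 with no filter, 0 with median-ratio scaling, no block or donor as the unit, and 4 with array weights or DESeq2. For gravity by day (0) they were 1 with quantile normalization, the depth covariate or plain CPM, and for gravity by culture (0) 1 with array weights.

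For HS/COL against COL (6) they were 1 with no filter, 3 with a mean of 100 or more, 2 with no block, 1 with donor as the unit, 21 with array weights, 20 with DESeq2 and 10 without low-depth libraries. For HS/COL against Suspension (91) they were 58 with a mean of 100 or more and 24 with donor as the unit, and for COL against Suspension (48) 23 with no block and 4 with donor as the unit. For the adipose donor (158) they were 89 with a mean of 100 or more, where fewer miRNAs are tested. For donor B against donor N (42) they were 64 with a pseudocount of 10, 69 with only the groups compared, 26 without low-depth libraries and 20 with the depth covariate. Of 144 list tests, 19 passed, 4 with an estimated correlation and 29 with fry. Reversed values were miR-1270 in rHS29/COL against rHS01/COL without low-depth libraries (-0.0059), let-7f-5p (0.17) and let-7b-5p (0.016) on HS/COL against Suspension with quantile normalization, and miR-16-5p in the adipose donor with the most abundant miRNA left out (-0.0095).

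Leaving out a library or a donor in turn gave 0 to 17 calls for gravity over all cultures, 1 to 7 on day 6 and 0 to 6 on day 9. Within cultures, gravity gave 0 to 0 in rHS29/COL, 0 to 7 in rHS01/COL, 0 to 23 in COL and 0 to 4 in Suspension. The range was 0 to 2 for gravity by day, 0 to 0 for gravity by culture and 0 to 1 for day. Between carriers it was 0 to 9 for HS/COL against COL and 0 to 0 for rHS29/COL against rHS01/COL. Against Suspension it was 47 to 97 for HS/COL and 13 to 54 for COL. For the 2 donor comparisons only single libraries were left out, with 139 to 167 calls for the adipose donor and 30 to 61 for donor B against donor N. List tests were repeated only with a donor left out and without the 2 donor comparisons, and 13 to 18 passed. That range covers fewer list tests than the main count and is not to be set against it. Of 197 called values of named miRNAs, 181 stayed called with edgeR, 190 with DESeq2, 174 with quantile normalization and 162 with no filter. With donor as the unit 33 of 114 stayed called. Depth limits scarce miRNAs, as the 7 libraries under 150000 counts hold few counts of them.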

Other observations

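The test of miR-1246 and miR-1290 against blood cell miRNAs was chosen after the result was seen, and the tests of neighbours, hairpin arms and miR-1973 with miR-4485-3p were planned. Neighbouring miRNA genes varied together between libraries: 322 pairs with hairpins within 10 kb on 1 strand had a median correlation of 0.204 with group and donor means removed, and 244 of them were above 0. In 1000 reassignments of the partners the median was 0.0456 and the highest 0.131. The pairs share 135 miRNAs and most lay on chromosome 14, so they are not independent and the median mostly describes that chromosome. Values there ranged widely, as miR-487b-3p had r = 0.90 with miR-654-3p and r = -0.68 with miR-382-5p. The 2 arms of a hairpin had a median correlation of 0.134 over 96 pairs, 63 of them above 0. In 1000 reassignments the median was 0.03996 and the highest 0.143, and 1 was as high as the arms. By the prediction written before the test, which asked for a value above all 1000, the arms were not shown to vary together. An undecided outcome for a value reached by few reassignments was added after the value was seen, and by it the question stays open. miR-1973 and miR-4485-3p, annotated in exons of MTRNR2L13 and MTRNR2L8, nuclear copies of mitochondrial ribosomal RNA genes, correlated at r = 0.887 over 47 libraries (rank correlation 0.889, adjusted permutation p = 2.0e-05, and r = 0.864 without the 2 libraries farthest from the median of miR-1973).

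miR-1246 and miR-1290, higher with carriers than in Suspension, did not vary with the blood cell miRNAs over the 36 carrier libraries (r = -0.029, permutation p = 0.867). With group and donor means removed, this argues against the same outside source as the main cause of variation in both sets between carrier libraries. It does not exclude a shared source for part of the rise over Suspension, as release by the cells was not measured. The highest level of miR-1246 in a library was 66169 scaled CPM, on rHS01/COL in microgravity on day 6 (donor B). The same library had the highest sum of values (1788211.9) and was named above for its high level of the liver miRNA.

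Labels were exchanged within matched libraries to count how often other splits gave as many calls, the real one included. For gravity over all cultures, on day 6 and on day 9 this was 1 of 100, with at most 0, 3 and 1 calls in the others. It was 2 of 32 in COL, where another split gave 9 calls, so chance is not excluded there. In Suspension it was 1 of 16, too few splits to decide (2 calls, at most 0 in the others). It was 1 of 100 for HS/COL against COL, HS/COL against Suspension, COL against Suspension, the adipose donor and donor B against donor N, with at most 1, 35, 25, 10 and 0 calls in the others. Where the real labels gave 0 calls, every split gives as many by construction and the count tests nothing: 32 of 32 in rHS29/COL and rHS01/COL, and 100 of 100 for gravity by day, gravity by culture, rHS29/COL against rHS01/COL and day 9 against day 6. Exchanged labels gave up to 10 calls in rHS01/COL and 14 for gravity by culture.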
